A study of Arabidopsis thaliana with 14 samples.

How the data were processed

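Messenger RNA, sRNA and bisulfite-treated DNA were sequenced from rosette leaves of control plants and of plants infested with aphids for 72 h. The 14 samples fall into 6 groups by their titles in the labels: 2 control and 2 aphid samples for RNA-seq, 2 and 2 for bisulfite sequencing, and 3 and 3 for sRNA sequencing. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was purified and made into directional libraries with NEBNext Ultra II, and small RNA was enriched with mirVana and made into libraries with the TruSeq Small RNA kit. Bisulfite samples were not analysed here.

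For RNA-seq, the authors deposited comparison tables, of genes and of transposable elements. Per the file headers, each table gives a base mean (a normalized signal averaged over libraries), a log2 fold change of aphid against control, its standard error, a Wald statistic (a score equal to the log2 fold change divided by its standard error), a p-value and an adjusted p-value. Trim Galore, Bowtie, Bowtie2, Bismark, HTSeq and DESeq2 and the build TAIR10 are named in the submitters' processing notes, with no version, and the role of each tool is not given in the sources used here. The standard errors had a ceiling of 0.573 in the authors' deposited table of genes, a property of fold changes shrunken towards 0. Shrinkage understates the change of genes with few counts. The deposited adjusted p-values were used as they stand, since no counts per library were used here; no test per gene was run. Of 20886 genes with a p-value, 5576 had no adjusted p-value, and their base means reached 4.24 at most in the authors' deposited table.

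For sRNA, the authors deposited 1 file per sample with each distinct sequence and its count, as whole numbers, not normalized. How reads were trimmed or filtered before counting is not given in the sources used here beyond the named tools. Sequences were 16 to 50 nt long. Of 17165 sequences with 100 or more counts over all libraries, 99.8% were listed in a single orientation, and several mature miRNAs were listed only as their reverse complement. The deposited orientation is therefore not the strand of the RNA. Each sequence was merged with its reverse complement before any step, which gave 2709564 distinct sequences, and no analysis of the first base was made. Sequences of an RNA and of its exact antisense partner cannot be told apart after this step.

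Genes were named from a table of the TAIR10.1 assembly, used for symbols only and without coordinates; 26719 of 27416 gene IDs matched it. The 17 gene lists, the 75 mature miRNA sequences and the tests were fixed before the data were examined. Lists were tested with cameraPR (limma 3.58.1, two-sided, preset correlation 0.01) on the authors' Wald statistic of all genes with an adjusted p-value, with Benjamini-Hochberg adjustment over the 17 lists. Counts of called members are given over all genes and adjusted over the list alone, the latter over every member with a p-value. Named genes were the 10 risen and 10 fallen with the smallest adjusted p among genes with a base mean of 50 or more and a symbol, up to 4 called members per list by absolute log2 fold change, and PR1, PAD3, PAD4, CYP81F2, VSP2, LOX2, PDF1.2, MYB51, WRKY33 and ICS1 whatever their result. For elements the rule took the 5 risen and 5 fallen with the smallest adjusted p, but at most 2 identifiers per direction are printed because no table pairs them with names. For miRNAs it took the 6 risen and 6 fallen with the smallest p among those called, and the 3 with the smallest p where fewer than 3 were called, and for sequences the 4 risen and 4 fallen with the smallest p. Loci of trans-acting sRNA, also in the rule, need a genome and were not analysed here.

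Counts per library size are given as CPM, after TMM factors for tested sequences and miRNAs and without them for the arthropod miRNAs. The sRNA counts were tested with edgeR 4.0.16 (R 4.3.3): total counts of each library as library sizes, TMM factors, filterByExpr with its defaults, and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. TMM factors ranged from 0.781 to 1.22. For miRNAs, the same library sizes and the factors from all tested sequences were used. Only exact mature sequences were counted, and 63 of the 75 had at least 1 count. They were written from general knowledge and not checked against a database, so a miRNA without a count may be a wrong sequence in the list, and shares of miRNAs cover only the sequences listed. The precision at this depth was checked on simulated data with the means and dispersion of the 28803 tested sequences. There, 200 sequences were changed, equally up and down. Of these changes, 2.0% of 2-fold, 44.0% of 4-fold, 70.0% of 8-fold and 82.0% of 16-fold ones were recovered. Unchanged sequences made up 5.71% of calls. The real data called 8980 sequences, 7654 of them risen, so the simulated shares need not hold for the real calls. For cameraPR, 72.0% of simulated lists shifted by 1 SD were called, on 15310 genes.

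Shares of the 20-nt to 25-nt classes were taken of all counts of 18 to 30 nt and compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 against 3. Libraries of the same group differed beyond sampling noise, with a chi-square per degree of freedom of 5.99 to 12.9, so none was treated as a repeat of another. Intervals and spreads do not correct for PCR copies, since no molecular identifiers are stated.

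Alternatives covered the threshold, the fold change, filters on low values, normalization (RLE, total counts), DESeq2 1.42.0, the preset correlation, the replicate number as a block and leaving out each sRNA library. A genome was not used here, so sRNA placement, sRNA at genes and elements, element superfamilies and sRNA against transcript change were not analysed here. A list of 30 miRNAs known from insects was written after the data were seen, and its division into those also known from vertebrates (11) and not (19) was made after their counts were seen. These sequences too were written from general knowledge and not checked against a database, and 23 of the 30 had at least 1 count. They were counted by sequences of 18 to 26 nt that start with their first 18 nt.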

Results

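The data came from rosette leaves of 5-week-old Arabidopsis thaliana plants of the Columbia-0 accession. Infested plants carried 40 wingless Myzus persicae, the green peach aphid, which feeds on phloem sap, under a net for 72 h, and the aphids were brushed off before the leaves were frozen. Infested leaves were compared with control leaves throughout, and the title of the series names epigenetic control and the regulation of defence as its subject. Messenger RNA was sequenced from 2 control and 2 infested samples, small RNA (sRNA) from 3 and 3, and bisulfite-treated DNA from 2 and 2; the bisulfite samples were not analysed here. For mRNA, the values were the authors' own comparison tables, so the depth of each mRNA library is unknown. The base means in the authors' deposited table of genes summed to 2292248 normalized counts. The sRNA libraries held 2624061, 2719998 and 2511327 counts in control replicates 1 to 3 and 3797406, 3262554 and 4410100 counts in aphid replicates 1 to 3. Nothing in the labels beyond the word bioreplicate in the titles shows whether replicates came from separate plants. P-values per gene, element, sequence, miRNA or size class therefore measure only the spread between these samples, which may be technical. Tests of gene lists and of gene families take genes as their units. Their p-values measure the spread between genes within the same comparison of 2 against 2 samples.

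The first comparison asked which genes changed in mRNA level with aphids. In the authors' deposited table, 265 genes rose and 2 fell at an adjusted p under 0.05, among 15310 genes with an adjusted p. RRTF1, a redox-responsive transcription factor, rose by a log2 fold change of 5.17 ± 0.50 (SE) in the authors' deposited table, with an adjusted p of 8.76e-21. LOX4, a lipoxygenase of jasmonate synthesis, rose 15.5-fold in the authors' deposited table, and ORA47, a transcription factor that activates jasmonate synthesis genes, rose by 4.17 ± 0.47 on the log2 scale. The heat shock factor HSFA2 rose by 4.53 ± 0.50 on the log2 scale in the authors' deposited table, the chaperone HSP101 by 4.51 ± 0.51 and HSP70 (AT3G12580) by 3.64 ± 0.43. WRKY40, a transcription factor of the immune response, rose by 3.72 ± 0.42 on the log2 scale in the authors' deposited table. The Nudix hydrolases NUDT4 and NUDT21 rose by 4.33 ± 0.46 and 3.79 ± 0.43 on the log2 scale, and the mitochondrial dicarboxylate carrier DIC2 by 4.09 ± 0.45, in the authors' deposited table. These are the 10 risen genes with the smallest adjusted p among those with a base mean of 50 or more and a symbol.

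No fallen gene met that rule, and both fallen genes are named after their values were seen. PAR1, a negative regulator of shade and auxin responses, had a log2 fold change of -1.99 ± 0.53 and AT4G38840 had -1.81 ± 0.48, with an adjusted p of 0.0127 each, in the authors' deposited table. The smallest absolute log2 fold change among the 267 called genes was 1.33 in the authors' deposited table. The Wald statistic had an SD of 0.736, taken from its interquartile range, and 63.7% of p-values were above 0.5 in the authors' deposited table, so its p-values ran high. The mitochondrial gene ATMG01080 and the nuclear gene AT2G07671 carried identical values (log2 fold change 1.51) in the authors' deposited table, so their reads could not be told apart; they too are named after their values were seen.

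Genes of jasmonate signalling, the hormone pathway of wounding, ranked above other genes as a set. Of 28 tested members, 9 rose and none fell in the authors' deposited table, 4 had a log2 fold change below 0, and 12 rose when adjusted over the list alone. LOX4 (3.95), CYP94B3 (3.52), LOX3 (3.45) and JAZ1 (2.99) had the largest log2 fold changes among called members in the authors' deposited table; CYP94B3 oxidises the active hormone and JAZ1 represses the pathway. VSP2, LOX2 and PDF1.2, marker genes of the jasmonate response, did not pass over all genes, with log2 fold changes of 0.90 ± 0.54, 1.12 ± 0.43 and 1.35 ± 0.50 in the authors' deposited table. When adjusted over the list alone, LOX2 (0.0228) and PDF1.2 (0.0166) passed by adjusted p in the authors' deposited table and VSP2 did not. The set test gave an adjusted p of 6.18e-23 (cameraPR, two-sided, on the authors' Wald statistic).

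Genes of ethylene synthesis and response also ranked above other genes as a set. Of 19 tested members, 7 rose and none fell in the authors' deposited table, 5 had a log2 fold change below 0, and 8 rose when adjusted over the list alone (set test, adjusted p = 3.71e-18). ACS6, an enzyme of ethylene synthesis, rose by 3.56 ± 0.42 on the log2 scale, and the response factors ERF104, ERF11 and ERF6 by 3.44, 3.34 and 3.04, in the authors' deposited table. Of the genes of pattern-triggered immunity, the defence set off by conserved microbial or damage signals, 8 of 20 tested members rose in the authors' deposited table, none fell, and 10 rose when adjusted over the list alone (set test, adjusted p = 1.14e-16). PHI-1 (3.15), WRKY22 (2.25), RBOHD (1.99), the oxidase of the reactive oxygen burst, and WRKY53 (1.93) led that list by log2 fold change in the authors' deposited table. In the list for reactive oxygen and redox response, 3 of 20 tested members rose in the authors' deposited table, over all genes and when adjusted over the list alone (set test, adjusted p = 1.03e-06). They were the zinc finger factors ZAT10 (13.0-fold) and ZAT12 (8.58-fold) and again RBOHD, which both lists hold, in the authors' deposited table.

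Of the genes of salicylic acid and systemic resistance, 2 of 24 tested members rose in the authors' deposited table, over all genes and when adjusted over the list alone, and 22 of the 24 had a log2 fold change above 0 (set test, adjusted p = 8.32e-05). They were SARD1 (1.73 ± 0.41) and CBP60G (1.65 ± 0.45), which activate the synthesis gene ICS1, by log2 fold change in the authors' deposited table. ICS1 itself (0.46 ± 0.46), PAD4 (0.35 ± 0.39), a regulator of resistance to this aphid, and the marker PR1 (0.49 ± 0.42) did not pass in the authors' deposited table. In the list for camalexin, an indole defence compound, 1 of 9 tested members rose in the authors' deposited table, over all genes and when adjusted over the list alone (set test, adjusted p = 0.00126). It was the regulator WRKY33, at 2.45 ± 0.40, while PAD3, the last enzyme of the pathway, had 0.36 ± 0.49 without passing, on the log2 scale in the authors' deposited table. None of 15 tested indole glucosinolate genes passed over all genes, and none when adjusted over the list alone, while 4 had an unadjusted p under 0.05, all of them higher, in the authors' deposited table from DESeq2. Among them, MYB51, a regulator of the pathway, had 1.11 ± 0.44, and outside them CYP81F2, which modifies these compounds, had 0.43 ± 0.54, on the log2 scale in the authors' deposited table. That list as a set ranked above other genes with an adjusted p of 0.0348, against 0.101 at a preset correlation of 0.05 and 0.0783 when ranked by log2 fold change.

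Genes of photosynthesis and of auxin response ranked below other genes. No photosynthesis gene passed, over all genes or when adjusted over the list alone, and 0 had an unadjusted p under 0.05, but 33 of 36 tested members had a log2 fold change below 0 in the authors' deposited table from DESeq2, with a median of -0.41 (set test, adjusted p = 4.95e-08). Antenna proteins such as LHCB5 (-0.70 ± 0.37) and LHCB1.2 (-0.68 ± 0.43) were among the lower members by log2 fold change in the authors' deposited table. No auxin gene of 20 tested passed over all genes, 1 was higher and 5 lower at an unadjusted p under 0.05, and 2 of the 25 with a p-value fell when adjusted over the list alone, in the authors' deposited table from DESeq2 (set test, adjusted p = 0.00177). SAUR20 (-1.66 ± 0.55) and SAUR21 (-1.51 ± 0.52), small auxin-induced genes of growth, had the lowest log2 fold changes of that list in the authors' deposited table and are named after their values were seen, like the antenna proteins.

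In the list for cell wall loosening and touch response, 2 of 19 tested members rose in the authors' deposited table and 4 rose when adjusted over the list alone. They were XTH22, a wall-modifying enzyme that rose 8.12-fold, and TCH2, a calmodulin-like protein that rose 4.30-fold, both known to be induced by touch, in the authors' deposited table. The median log2 fold change of that list was -0.05 and its mean 0.20, and the set test, which pointed up, did not pass (adjusted p = 0.430). No member passed, over all genes or when adjusted over the list alone, in the lists for aliphatic glucosinolates (15 tested, set test adjusted p = 0.734), abscisic acid (18, 0.590), senescence (16, 0.124) and RNA silencing and DNA methylation (38, 0.0853) in the authors' deposited table from DESeq2. At an unadjusted p under 0.05, these lists held 0, 1, 2 and 0 members in the authors' deposited table. No member passed, in either way or at an unadjusted p under 0.05 (0 members), among markers of phloem and vasculature (13 tested, set test adjusted p = 0.831), epidermis and guard cells (12, 0.590) and inflorescence (3, 0.590) in the authors' deposited table from DESeq2. For abscisic acid the median log2 fold change was 0.0032 while the mean (-0.00092) and the test pointed down, and for epidermis and guard cells the median was 0.07 while the mean (-0.0084) and the test pointed down. A correlation between genes could not be estimated without values per library, so no list call was tested with an estimated correlation.

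**Figure D1:**
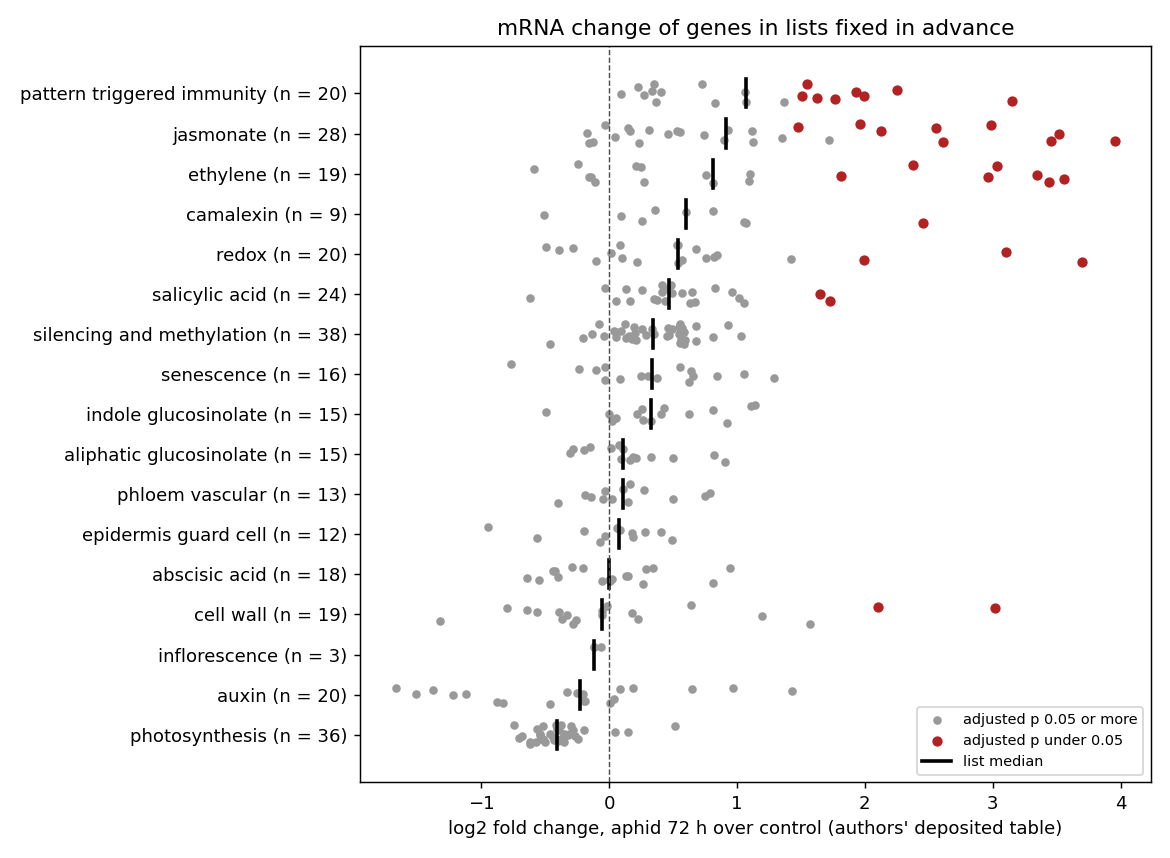
Log2 fold change of each tested gene (x axis, aphid 72 h over control, from the authors' deposited table) in each of the 17 lists (y axis), with genes past an adjusted p of 0.05 in red, others in grey, and the list median as a black bar. The medians run from 1.07 for pattern-triggered immunity to -0.41 for photosynthesis, and every red point lies above 0.

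Gene families were also compared by the letters that begin their symbols, a grouping chosen after the data were seen. Heat shock proteins (HSP), ethylene response factors (ERF), WRKY factors and JAZ repressors held a larger share of risen genes than other genes with a symbol. In the authors' deposited table, 8 of 20 HSP genes rose (adjusted p = 6.92e-07), as did 7 of 16 ERF genes (1.74e-06), 6 of 41 WRKY genes (0.0155) and 3 of 9 JAZ genes (0.0482), against 141 of all 7049 tested genes with a symbol. Only names that the symbol table gives as symbols were counted, which leaves out genes named there by synonym, such as ERF105, which rose by 2.37 ± 0.52 on the log2 scale in the authors' deposited table and is named after its values were seen. The risen HSP genes included the small heat shock proteins HSP17.6A (3.64 ± 0.55) and HSP17.4 (2.22 ± 0.56) and the chaperone HSP90.1 (1.93 ± 0.46), by log2 fold change in the authors' deposited table. These p-values came from Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over 320 stems of at least 5 tested genes. Members of such families have similar sequences, so reads could have been split between them in the authors' counting.

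The second comparison asked whether transcripts of transposable elements changed. A single element, AT1TE89775, rose and none fell among 1448 tested in the authors' deposited table, and 29740 of the 31188 elements listed had a base mean of 0. Its log2 fold change was 4.09 ± 0.71, with a base mean of 26 and an adjusted p of 1.39e-05, in the authors' deposited table. The next element, AT5TE49540, had 2.03 ± 0.54 on the log2 scale with an adjusted p of 0.105, and the lowest, AT5TE18980, had -1.54 ± 0.60, in the authors' deposited table. At an unadjusted p under 0.05, 19 elements were higher and 3 lower in the authors' deposited table from DESeq2, against 72.4 expected if p-values were uniform. They were not uniform: 81.2% were above 0.5 in the authors' deposited table. The Wald statistic of elements had an SD of 0.428 there, taken from its interquartile range. The shortfall against 72.4 therefore decides nothing about elements. Between base means of 0.189 and 19.3, 0.582% of 1375 elements and 0.994% of 11171 genes were higher at an unadjusted p under 0.05 in the authors' deposited tables; this difference was not tested. The median base mean of tested elements was 0.629 in the authors' deposited table. With a base mean of 10 or more and p-values adjusted again, 4 elements rose and none fell in the authors' deposited table. With the Wald statistic of the authors' deposited table scaled to its own spread, an alternative chosen after the data were seen, 37 elements were called higher and 18 lower.

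The third comparison asked whether the sizes of sRNA changed, since plant silencing pathways make sRNAs of different lengths. Length alone does not show that a sequence is a product of silencing, and no sequence was placed on a genome. In control libraries, 16-nt sequences held 20.6% of all counts and 24-nt sequences 4.99%. The 24-nt class, the length of plant sRNAs that guide DNA methylation, made up 10.1% ± 0.57 (SD, n = 3) of counts of 18 to 30 nt in control and 7.05% ± 0.83 (SD, n = 3) in infested leaves. The 21-nt class, the length of most miRNAs, made up 9.47% ± 0.49 and 7.97% ± 0.51 (SD, n = 3 each). The 22-nt and 23-nt classes made up 9.38% ± 0.70 and 8.11% ± 0.02 in control and 7.14% ± 0.56 and 6.33% ± 0.54 in infested leaves (SD, n = 3 each). The 20-nt class had 9.25% ± 0.30 and 8.64% ± 0.30, and the 25-nt class 6.71% ± 0.76 and 5.04% ± 0.54 (SD, n = 3 each). Each of the 6 classes gave p = 0.1 in a two-sided exact permutation test, the smallest that 3 samples against 3 allow, and an adjusted p of 0.1, so none could pass the threshold. As a share of 20 to 25 nt only, the aphid minus control difference was 3.11 percentage points for the 20-nt class and 1.05 for the 21-nt class, the reverse direction, and -2.35 for the 24-nt class. With distinct sequences counted once each, the 20-nt difference was 1.2, again the reverse direction. As a share of counts of all lengths, seen after the choice of 18 to 30 nt, the 20-nt class had 4.56% in control and 4.66% in infested leaves (two-sided exact permutation p = 0.4), the 21-nt class 4.68% and 4.30% (p = 0.3) and the 24-nt class 4.99% and 3.81% (p = 0.1, the smallest possible).

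**Figure D2:**
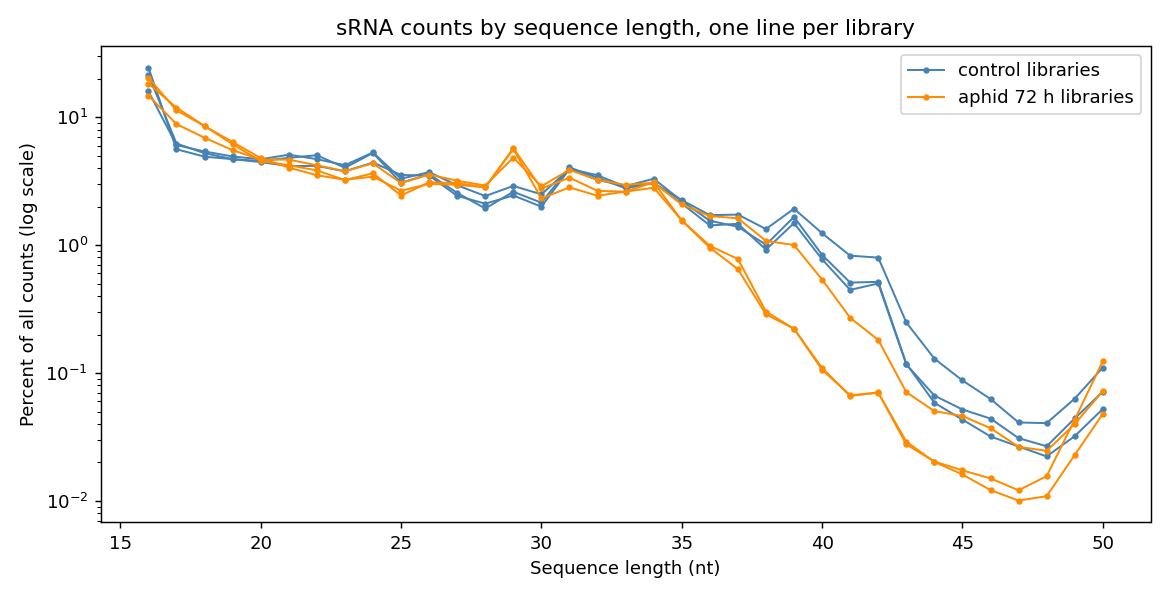
Percent of all counts in each library (y axis, log scale) by sequence length in nt (x axis), with 3 control libraries in blue and 3 aphid libraries in orange. At 29 nt the aphid libraries average 5.39% and the control libraries 2.65%, and from 38 to 43 nt they average 1.57% and 5.09%.

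The fourth comparison tested each sRNA sequence. Of 28803 sequences tested, 7654 rose and 1326 fell with aphids (edgeR quasi-likelihood test, adjusted p under 0.05). Among the shortest, 53.0% of tested 16-nt and 54.4% of tested 17-nt sequences rose, against 16.3% at 21 nt and 13.6% at 24 nt. At 29 nt, 24.2% rose, against 19% at 28 nt and 16.5% at 30 nt. Among long ones, 66.1% of tested 40-nt and 80.8% of tested 41-nt sequences fell, against 2.16% at 24 nt. Risen sequences took 1.80% to 2.18% of the counts of control libraries and 15% to 26.6% of those of aphid libraries. In the same libraries, 19 listed miRNAs known from arthropods and not from vertebrates made up 32.0 ± 28.9 CPM of all counts in control and 1005 ± 370 in infested leaves (SD, n = 3 each), and 15.4 in control without control replicate 1. The list was divided in this way after its counts were seen. Most of the sum over the 19 came from bantam, an insect miRNA, with 2131 to 5226 of their 2755 to 6281 counts in aphid libraries. All 30 listed miRNAs made up 404 ± 82.1 CPM in control and 1643 ± 502 in infested leaves (SD, n = 3 each).

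Sequences are given by length and level, since no genome was used here and their origin is not known. Among the 4 risen sequences with the smallest p, an 18-nt sequence had 9.40 ± 2.23 CPM in control and 1090.0 ± 442 in infested leaves (SD, n = 3 each, edgeR adjusted p = 2.90e-06). A 17-nt sequence had 11.4 ± 2.47 and 1399 ± 642 CPM (SD, n = 3 each, edgeR adjusted p = 2.90e-06). The others were a 16-nt sequence with 1 count in each control library and 323 to 527 in aphid libraries, and an 18-nt sequence with 2 in each and 356 to 447. Of the 4 fallen sequences with the smallest p, a 26-nt sequence had 214 ± 61.4 and 20.6 ± 1.33 CPM and a 41-nt sequence 75.3 ± 8.78 and 5.76 ± 1.99 (SD, n = 3 each, edgeR adjusted p of 1.14e-05 and 9.43e-06). A 40-nt sequence had 82 to 85 counts in control and 5 to 9 in aphid libraries, and a 39-nt sequence 50 to 55 and 2 to 6. The number of sequences called was 14214 without control replicate 2, 14444 without aphid replicate 1 and 18845 with no filter on low counts. More sequences were tested in these settings, 31671 to 41212 when leaving out a library and 2709564 with no filter, against 28803. The counts called there are therefore not over the same sequences. The number that fell was 2943 without control replicate 2, 3072 without aphid replicate 1, 814 without aphid replicate 3, 2090 with total counts only and 578 with no filter. It was 738 with TMM over sequences with 10 or more counts in every control library, chosen after the data were seen. The number that rose was 11943 without control replicate 1, 11909 without control replicate 3 and 18267 with no filter.

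The fifth comparison tested mature miRNAs, the short RNAs that guide cleavage or repression of target mRNAs. None of 35 tested passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, where 7 had an unadjusted p under 0.05, and DESeq2 also called 0, with 8 unadjusted. The log2 fold change was below 0 for 29 of the 35, with a median of -0.59, and in 8 every aphid library lay under every control library. For a single miRNA, chance gives no overlap in 10% of cases, counting both directions. The miRNAs share a scaling factor per library and can move together, so that percent is no test of the 8. The 3 with the smallest p, none of which passed, were miR158a-3p and both strands of miR168a, which targets the silencing protein AGO1. For miR158a-3p, 1042 ± 208 and 585 ± 111 CPM (SD, n = 3 each) gave a log2 fold change of -0.83 ± 0.26 (SE) and an edgeR adjusted p of 0.0652. For miR168a-3p, 19.5 ± 5.75 and 9.15 ± 2.17 CPM (SD, n = 3 each) gave -1.09 ± 0.40 (SE), and for miR168a-5p 25.3 ± 8.51 and 12.1 ± 5.00 CPM gave -1.08 ± 0.40 (SE), with an edgeR adjusted p of 0.0844 for each. The only tested miRNA with every aphid library above every control library was miR163, with 37.2 ± 1.25 and 53.1 ± 11.2 CPM (SD, n = 3 each, edgeR adjusted p = 0.373), named after its values were seen.

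Listed miRNAs together made up 0.375% to 0.499% of counts in control libraries and 0.214% to 0.290% in aphid libraries. The median log2 fold change ran from -1.01 without control replicate 2 to -0.24 with TMM over sequences with 10 or more counts in every control library, the latter chosen after the data were seen. Scaling on the miRNAs alone, which centres them and so decides nothing about their direction, gave -0.12. Scaling on total counts alone called 7 miRNAs, a filter of 10 or more counts in at least 3 libraries called 1, and leaving out control replicate 2, control replicate 3 or aphid replicate 2 called 2, 5 and 4, and the replicate number as a block called 4 (11 at an unadjusted p under 0.05), all of them fallen.

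**Figure D3:**
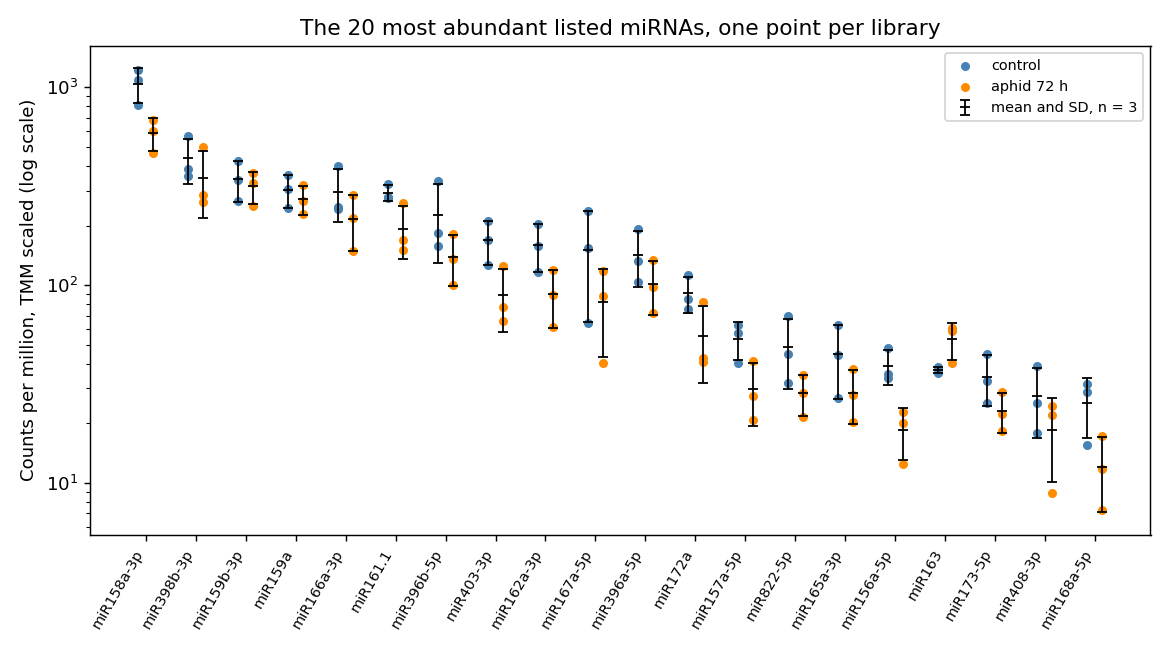
CPM after TMM scaling (y axis, log scale) of the 20 tested miRNAs with the highest control mean (x axis), with a point per library, control in blue and aphid 72 h in orange, and bars for the mean and SD of 3 libraries. Most means are lower with aphids, as for miR158a-3p (1042 against 585).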

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

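All tests in this part except that of plant RNA breakdown were chosen after the result was seen, as was the division of the arthropod miRNAs.

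A signal appeared in sequences outside the plant miRNA comparison: 19 listed miRNAs known from arthropods and not from vertebrates made up 1005 ± 370 CPM of all counts in aphid and 32.0 ± 28.9 in control libraries (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Without control replicate 1, which held 65.2 CPM, the control mean was 15.4. Most of that sum came from bantam, an insect miRNA, which had 2131 to 5226 counts in aphid and 23 to 157 in control libraries. The 19 together had 2755 to 6281 and 32 to 171 counts, and 15 of them had at least 1 count. Sequences of 29 nt, outside the size classes compared, made up 5.39% ± 0.49 of all counts in aphid and 2.65% ± 0.23 in control libraries (SD, n = 3 each, exact permutation p = 0.1).

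A set of 6062 sequences was at least 10-fold higher in every aphid library than in any control library, against 17 in the mirrored direction. Both counts cover only sequences with at least 2 CPM of all counts in every library of the higher group. The set of 6062 held 8.42% to 16.2% of the counts of aphid and 0.162% to 0.223% of those of control libraries. The larger totals of the aphid libraries are argued against, since the set redrawn after thinning every library to 2511327 counts had 91.7% of its size. For breakdown of plant RNA that control leaves also hold, 3610 set sequences of 16 to 20 nt were sought inside longer control sequences. Of them, 39.9% were found, against 96.5% of uncalled sequences matched by length and level in aphid libraries, or 41.4% of that share. The set was chosen for low control levels, and the uncalled sequences for similar levels in both groups. The gap follows in part from that choice, so the test decides nothing about breakdown. Within the set, RNA of the aphids and plant sRNA induced by aphids cannot be told apart without a genome. Of the set, 51.8% had no count in any control library. All 30 listed miRNAs of arthropods were 2.61 times higher in the lowest aphid library than in the highest control library, between the bounds set. That ratio was 11.1 for the 19 not known from vertebrates (37.96 without control replicate 1) and 1.28 for the 11 others, a division made once their counts had been seen. Among single members, miR-14 had 5 to 8 counts in control and 462 to 862 in aphid libraries. For miR-276 there were 0 and 22 to 27, while let-7 and miR-1 were not higher by CPM. Such values would follow from aphid RNA in the infested samples. They do not give the share of the set that came from aphids, and the listed sequences were not checked against a database.

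The gains of the 20 sequences of 29 nt that gained most summed to 91.6% of the net gain at that length. Falls of other 29-nt sequences were subtracted in that net gain, so the share of all gains is smaller. The first had 986 to 1708 counts in control and 19288 to 32200 in aphid libraries. Longer sequences that start or end with it were summed only where they had 100 or more control counts. They had 9722 ± 847 CPM of all counts in control and 10924 ± 1182 in aphid libraries (SD, n = 3 each). Those of the next had 21109 ± 3944 and 16510 ± 1971 and of the one after it 4468 ± 468 and 4206 ± 560 (SD, n = 3 each). Longer sequences found mainly in aphid libraries were left out by that choice, so these levels do not show that longer forms stayed level. A shift in the size range selected for the libraries is argued against as the whole cause: it would move sequences of the same length alike, but the median ratio to control of the 952 tested 29-nt sequences was 1.296, 0.794 and 0.898 in aphid replicates 1 to 3, against 1.82, 2.16 and 2.13 for the whole 29-nt share. RNA of the aphids cannot be told apart from plant RNA here: 13 of the 20 start or end a longer sequence with 100 or more control counts and 7 do not, but RNA conserved between organisms can share 29 nt. A change in how infested leaves cleave longer RNA stays open, as untested.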

How the results depend on the processing

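Centring the fold changes, scaling the Wald statistic, restricting lengths, leaving out the sequences near-absent from controls and scaling on control-detected sequences or on miRNAs alone were chosen after the result was seen. The 267 called genes became 206 to 358 over the alternatives, with 96.6% to 100% of them risen. Called elements went from 1 to 4 with a base mean of 10 or more and to 55 with the Wald statistic scaled to its own spread. Of the 17 lists, 9 passed; indole glucosinolates no longer passed at a preset correlation of 0.05 (0.101) or ranked by log2 fold change (0.0783), where RNA silencing and DNA methylation passed (0.0485), and the same 9 passed with a base mean of 10 or more; the phloem list turned down with a base mean of 10 or more (adjusted p = 0.923), without passing either way. Called sRNA sequences (8980) became 18845 with no filter, where more were tested, and 1420 among 20 to 24 nt and 5352 among 18 nt or more, where fewer were. They became 7760 to 14444 when leaving out each library, where 31671 to 41212 were tested against 28803. The total stayed within 1.5 times under every other setting. Fallen sequences (1326) became 2090 with total counts only, 738 with TMM over sequences with 10 or more counts in every control library, 742 among 18 nt or more, 96 among 20 to 24 nt, 578 with no filter and 814 to 3072 when leaving out each library. The median log2 fold change of all sequences moved from 0.05 to -0.12 with total counts only and to 0.40 with TMM over sequences with 10 or more counts in every control library. Called miRNAs went from 0 to 7 with total counts only and 1 with a filter of 10 or more counts in at least 3 libraries, which was planned as the stricter filter but kept 36 miRNAs against 35, and to 0 to 5 when leaving out each library, all fallen. Except where stated, the cause was not tested.

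For the size classes (aphid minus control, percentage points), the 20-nt, 21-nt, 22-nt, 23-nt and 25-nt differences became 3.11, 1.05, -0.763, -0.301 and -0.738 with a denominator of 20 to 25 nt. With distinct sequences the 20-nt to 25-nt differences became 1.2, -0.838, -1.55, -3.26, -4.89 and -1.02, and without sequences counted once the 20-nt, 23-nt and 24-nt differences became -1.03, -1.18 and -2.24. Leaving out each library gave -0.774 to -0.441 (20 nt), -1.78 to -1.29 (21 nt), -2.53 to -1.84 (22 nt), -2.09 to -1.59 (23 nt), -3.51 to -2.73 (24 nt) and -1.95 to -1.23 (25 nt). The 24-nt difference stayed below 0 in all of these and was -2.50 without the sequences near-absent from controls; the cause of the moves was not tested.

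The values do not settle whether replicate numbers pair the sRNA samples. Deviations of same-numbered samples correlated at -0.111, -0.0772 and 0.390, and those of differently numbered samples at -0.257 to 0.304. With the replicate number as a block, 9750 sequences and 4 miRNAs were called, and the sign-flip test of the size classes (differences of -0.604, -1.49, -2.24, -1.78, -3.04 and -1.67 for 20 to 25 nt) cannot go below 0.25. No paired analysis was possible because no values per library were used for the RNA-seq tables, where leaving out a replicate could not be done either. Alternatives that place sRNA on a genome or leave out rRNA, tRNA and organelle sequences, and those for element superfamilies, were not run. The 10 splits of the 6 sRNA libraries are too few for a share under 0.05: the real split called 8980 sequences and the highest other 0, and for miRNAs 0 and 1.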

Other observations

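The tests of 38 to 43 nt, of the miRNAs of animals, of a shift of scale, of handling and of feeding were chosen after the result was seen.

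Of the genes for RNA silencing and DNA methylation, 33 of 38 tested had a log2 fold change above 0 in the authors' deposited table, with none called; ranked by log2 fold change in place of the Wald statistic the list had an adjusted p of 0.0485, and over its settings the adjusted p ran from 0.0485 to 0.269. Fragments of 38 to 43 nt made up 5.09% ± 1.13 of all counts in control and 1.57% ± 1.36 in aphid libraries (SD, n = 3 each, exact permutation p = 0.1). Aphid replicate 1 held 3.14%, and aphid replicates 2 and 3 held 0.797% and 0.782%. The 11 listed miRNAs known from both arthropods and vertebrates made up 372 ± 63.1 CPM of all counts in control and 638 ± 132 in aphid libraries (SD, n = 3 each, exact permutation p = 0.1). The sum hides members that differ: let-7 had 70.1 to 110.1 CPM in control and 49.4 to 88.9 in aphid libraries and miR-1 had 155 to 191 and 141 to 180, while miR-9a had 24.7 to 53.0 and 132 to 279 and miR-7 had 50.2 to 62.9 and 117 to 276.

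Nearly all called genes rose. A shift of scale left in the deposited fold changes is argued against as the whole cause: it would move all genes alike, but the median of 15310 tested genes was 0.0307 with a spread of 0.427 (SD from the interquartile range), while the smallest called change was 1.33, on the log2 scale in the authors' deposited table. A change in total mRNA that the authors' normalization removed would not be seen in these values. Handling, brushing and harvest of the infested plants and feeding by aphids for 72 h, with which 265 genes rose, cannot be told apart, since the labels describe the net and the brushing for infested plants only and do not say how control plants were handled. Of 8 slower defence markers, 0 passed over all genes in the authors' deposited table from DESeq2 and 3 had an unadjusted p under 0.05; all 8 had a log2 fold change above 0 (0.36 to 1.35) and PDF1.2 passed when adjusted over the jasmonate list alone, so they decide nothing.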
